A study of Arabidopsis thaliana with 4 samples.

How the data were processed

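The data were taken as deposited: 1 Affymetrix ATH1 array for each of 4 groups of Arabidopsis thaliana plants, namely unwounded wild type (wt), systemically wounded wt, unwounded opr3 and systemically wounded opr3. The ATH1 array measures transcripts with probe sets, groups of short oligonucleotides near the 3' end of a transcript. Per the labels' protocols, plants were 6 weeks old and grown at 21 °C with 10 h of light and 14 h of darkness. Some rosette leaves were crushed across the midvein with tweezers, and RNA came from the leaves of these plants that had not been crushed, 2 h later. Total RNA was isolated with a column kit, and 10 ug of it was turned into biotin-labelled cRNA. The treatment text of the opr3 wounded sample speaks of wt plants, and its group was taken from its title. The accession background of either line was not given in the sources used here.

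The deposited values are log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalization and summarisation of probes) and Partek, both named without a version in the submitters' processing notes. The genome build and probe set annotation the authors used were not given in the sources used here. Column means lay between 5.8954 and 5.8956, and column medians between 5.36 and 5.42. Raw probe intensities were not analysed here, so the background correction could not be varied. RMA draws low values together, so folds of weakly expressed genes are understated.

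The table held 22810 probe sets, of which 64 were array controls and 22746 measured plant transcripts. Gene names came from the platform annotation in the reference tables, updated through gene identifiers in the gene table of assembly TAIR10.1. That annotation paired 13513 probe sets with 1 gene, of which 13436 matched the gene table, and 503 with several genes. The other 8730 plant probe sets were not listed in it and are unnamed here, which does not mean that they lack a gene. They include a large part of the jasmonate genes fixed for study, so counts cover all probe sets whereas names cover only part of them. No coordinates are given, because the files name no build.

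A probe set was used where its highest value over the 4 arrays reached the 40th percentile of all values, a log2 value of 4.73, and 14612 probe sets did so. Of these, 7984 had 1 named gene. For each comparison the log2 value of 1 array was subtracted from that of another, and a probe set counted as higher or lower where the difference was at least 2-fold (log2 difference of 1). Comparisons were the wounding response in wt, the wounding response in opr3, opr3 against wt in control plants, opr3 against wt in wounded plants, and the difference between the wounding responses (opr3 minus wt). With 1 array per group there is no measure of spread between plants, so no test, p-value or standard error was computed. Precision is limited by the number of arrays.

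These choices were made before the data were examined, as were the gene lists, the rule for named genes and all alternatives except those described as chosen afterwards. The rule took, in each of the first 3 comparisons named and in the difference of the responses, the 12 largest differences upward and the 8 largest downward among named probe sets past the limit. It added OPR3 and up to 4 members of each described list. Of 405 members written in 34 gene lists and marker sets, 60 were named on the array and 45 passed the filter. Medians were computed for the 8 lists with at least 3 such members, with 1 probe set per gene (the highest mean). Each median was ranked among those of 10000 random lists of the same size, drawn from 7892 named genes in 20 classes of mean expression. The ranks describe these arrays only.

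In 11 lists no member was named on the array: JAZ repressors, salicylate response, ascorbate and polyamines, morning clock genes, sugar starvation and darkness, cell division, and the markers of trichome and epidermis, phloem, xylem, flower and seed. They were therefore not analysed here, and 15 further lists had named members but fewer than 3 that passed.

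The steps were tested on simulated data for the wt wounding response with 14612 probe sets and an assumed noise SD of 0.136 (log2). Past the 2-fold limit lay 2 of 50 probe sets changed by 1.5-fold, 23 of 50 changed by 2-fold, 50 of 50 changed by 3-fold and 50 of 50 changed by 4-fold. Of 14412 unchanged probe sets none passed in the wt wounding response and 2 in the difference of the responses, and 193 of 200 unchanged lists ranked within the central 95% of random lists. The noise SD came from the central spread of the differences between the 2 control arrays, and the noise was normal and equal for all probe sets. Heavier tails are therefore left out, so the low counts of unchanged probe sets say little about false calls in the data. True noise between plants may be larger than assumed.

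Alternatives were centring each array on its median, quantile normalization, cyclic loess, no filter, a filter at the 60th percentile, limits of 1.5-fold and 3-fold, and leaving out probe sets with a suffix for possible cross-hybridization. For lists, the mean replaced the median, or all probe sets of a gene were used. Plastid-encoded genes were left out as an alternative chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 (normalization only) were used.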

Results

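Expression was measured in leaves of wt and opr3 plants, unwounded or 2 h after other leaves of the same rosette had been wounded, on 1 array per group. OPR3 encodes 12-oxophytodienoate reductase, which converts the cyclopentenone OPDA towards jasmonic acid, so the design asks which parts of the systemic wound response differ in a plant with a lesion in this step. The groups have no replicates, and none of the differences below has a replicate check. Every pair of arrays correlated with Pearson's r between 0.965 (wt wounded and opr3 control) and 0.993 (wt control and opr3 control) across probe sets, which are not independent replicates. No probe set was named OPR3 in the annotation used, so the level of the mutated gene was not analysed here. The named probe sets do not show which line carries the lesion, and no unnamed probe set could be assigned to OPR3 here. For the pairing of arrays by line, AT5G02140 was at 4.33 and 4.28 in the wt arrays and 7.13 and 6.89 in the opr3 arrays, and AT5G01015 at 7.29 and 7.08 and at 4.58 and 4.47, which puts the opr3 wounded array with opr3 control, as its title does. These genes were picked from the control arrays after the values were seen. Folds that rest on a value under the filter level of 4.73 in any array of the comparison, near background, are given with the word about, and their size and order are approximate.

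In wounded wt the leaves that had not been crushed carried much higher transcript levels of jasmonate-modifying enzymes than leaves of control plants. AT2G38240 was 44.1-fold higher, JRG21 about 25.8-fold and AT5G05600 16.4-fold, all members of the family of jasmonate oxidases, which hydroxylate and so inactivate jasmonic acid. JMT, the jasmonate methyltransferase, was about 6.98-fold higher, and BSMT1, which makes methyl salicylate and methyl benzoate, about 30.7-fold. The list of jasmonate turnover genes, with 4 of its 11 members measured, had all 4 at least 2-fold higher and a median log2 difference of 4.36, above all 10000 random lists. The filter left out a further named member, AT3G11180, and without the filter the median was 4.04. In the other 3 arrays BSMT1 (3.97, 3.86 and 3.61), JRG21 (4.44, 4.03 and 4.1) and JMT (4.33, 3.56 and 4.63) lay under the filter level, so JRG21 and JMT entered the list only through their level in wounded wt. Highest of the named genes was AT5G62360 at 46.9-fold, a member of the pectin methylesterase and invertase inhibitor family.

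Among named genes, single members of other families followed in wt. AT4G30650, of the low-temperature and salt responsive protein family, was 18.9-fold higher, AT3G51450 17.3-fold, AT1G15010 16.5-fold and AT5G55180, a glycosyl hydrolase, 15.2-fold. AT2G43550 and the jacalin-related lectin gene JAL23 were each 14.8-fold higher, and AT5G06570 was about 14.4-fold higher. Among dehydration and cold genes, COR15A was 3.59-fold, COR47 2.64-fold and COR15B 2.35-fold higher. These were the only measured members of the 25 written in the abscisic acid list. All 3 were past the limit (median 1.4, percentile 99.9). Of 4 measured touch and calcium genes, CML41 was 2.28-fold higher while CML42 (1.97-fold) and CML38 (1.79-fold) lay just under the limit and CML23 had a log2 difference of -0.24. The median of these calmodulin-like genes was 0.91, at percentile 99.8 of random lists, and 0.68 without the filter.

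The lists of glucosinolate, tryptophan and sulfur genes had 2 measured members each, too few for a median, and in wounded wt both indole glucosinolate and tryptophan genes, 1 of 2 aliphatic glucosinolate genes and 1 of 2 sulfur genes were past the limit. UGT74B1, a glucosinolate glucosyltransferase, was 2.55-fold higher and AT2G04400, the indole-3-glycerol phosphate synthase of tryptophan synthesis, 2.86-fold. BCAT4, which starts the chain elongation of methionine for aliphatic glucosinolates, was 2.42-fold higher and AT2G31790 1.86-fold. APS3, an ATP sulfurylase, was 2.69-fold higher, and SIR, the sulfite reductase, 1.66-fold. OPCL1, a ligase of jasmonate synthesis, was 2.45-fold higher, whereas AIM1 of the same list had a log2 difference of -0.23. None of the 4 measured MYC-branch genes, out of 17 written, was past the limit in wounded wt (median 0.24, percentile 89.0). The rest of that list had no named probe set, so its medians say little about the branch as a whole.

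The lowest named transcripts in wounded wt were plastid-encoded. Photosystem I gene psaA was 24.4-fold lower, atpH of the plastid ATP synthase 8.44-fold, psbD of photosystem II 6.62-fold, psaC 6.47-fold, ndhH of the NDH complex 6.28-fold, accD 4.98-fold, ycf4 4.50-fold and psbB 4.15-fold. Of 69 plastid-encoded probe sets, 23 were at least 2-fold lower and none higher, with a median of -0.45, although 20 lay within 0.25 of no difference. In the same array the spiked-in bacterial transcripts had a mean 5' minus 3' log2 difference of -2.00 over 8 probe set pairs, against -1.16 in wt control, -1.27 in opr3 control and -1.29 in opr3 wounded. The nuclear photosynthesis genes RCA, PRK and LHCB4.1, 3 of 26 written, had a median of -0.01, at percentile 78.3. RCA (13.47 in wt control) and LHCB4.1 (13.56) lay near the highest value of that array (13.69), where a difference may not show. PRK was at -0.33.

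In all, 576 of 14612 probe sets were at least 2-fold higher in wounded wt and 261 lower, of which 257 and 148 had a named gene. The central 95% of log2 differences ran from -0.92 to 1.34. Without plastid-encoded genes the lower count was 238. At a 1.5-fold limit the counts were 1216 and 1243, so the excess of higher over lower probe sets depended on the limit.

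**Figure D1:**
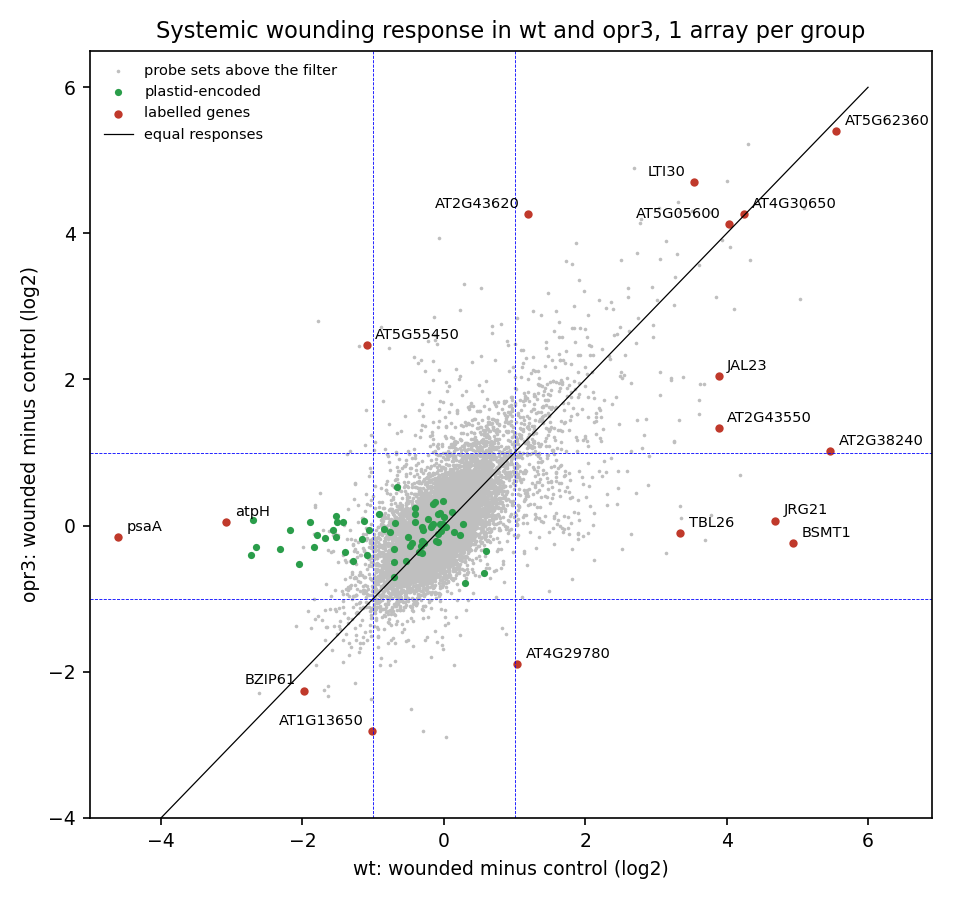
Log2 difference between wounded and control plants in wt (x axis) and opr3 (y axis) for 14612 probe sets, each a point, with plastid-encoded probe sets in green, selected genes labelled in red, the line of equal responses and dashed lines at 2-fold. AT5G62360 lies near the line at 5.55 and 5.40, whereas BSMT1 lies at 4.94 in wt and -0.24 in opr3.

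In wounded opr3, genes of dehydration and cold stress were higher than in opr3 control. LTI30, a dehydrin, was about 25.9-fold higher, COR15A 8.02-fold, COR15B 4.24-fold and COR47 3.10-fold. The abscisic acid and dehydration list had a median of 2.08, above all 10000 random lists. Only these 3 COR genes of its 25 written members were measured. AT5G62360 was again the highest named gene at 42.1-fold. AT1G51090 was about 19.8-fold higher, AT5G47330 19.7-fold, AT2G43620 of the chitinase family 19.3-fold, AT4G30650 19.2-fold, AT1G14780 about 18.4-fold and the beta-glucosidase gene BGLU40 17.7-fold. AT5G05600 was 17.5-fold higher, AT5G55180 15-fold, PRN, which encodes a pirin, 14.9-fold, and AT5G55050 14.6-fold.

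Of the jasmonate turnover genes in opr3, AT5G05600 had its wt-sized difference, JMT was about 2.09-fold and AT2G38240 2.03-fold higher, and JRG21 differed by a log2 value of 0.07. Their median of 1.04 ranked at percentile 99.9, and their mean was 1.57. GH3.3, an auxin-conjugating enzyme, was 6.00-fold higher (about 4.07-fold in wt). The 3 auxin response genes measured of 10 written had a median of 0.67 at percentile 98.7, with IAA29 at -0.44 and WES1 at 0.67. In the MYC-branch list the glutaredoxin gene GRX480 was about 4.73-fold higher, while MYC3, MYC4 and THI2.1 had log2 differences of 0.32, -0.03 and -0.32. The median of the 4 genes was 0.14 (percentile 74.4) and the mean 0.55. THI2.1 lay under the filter level in both opr3 arrays, so its difference is approximate. The touch and calcium genes had a median of 0.05, at percentile 62.5, but of 0.58 with the stricter filter at the 60th percentile, which leaves fewer genes, and CML41 alone among the 4 was past the limit at about 2.31-fold.

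Lower in wounded opr3 were AT1G13650 (7.05-fold), the bZIP transcription factor gene BZIP61 (4.78-fold), AT3G07010 (4.75-fold) and AT4G27280 (4.56-fold). BHLH101, a regulator of the iron deficiency response, AT1G05575, AT4G37220 and AT4G29780 were lower by about 3.73 to 3.76-fold. Before wounding, AT4G29780, AT1G05575 and AT4G37220 were already 5.64-fold, 2.73-fold and 2.11-fold higher in opr3 than in wt. After wounding these genes lay within 2-fold of wt, so their decrease rests largely on the single opr3 control array. AT4G27280 was 1.76-fold higher in opr3 controls, whereas BZIP61 and BHLH101 differed by 1.05-fold and 1.04-fold there. None of the 69 plastid-encoded probe sets was past the limit in either direction, and their median was -0.08. Across all probe sets 708 were at least 2-fold higher and 245 lower, of which 328 and 135 had a named gene. The central 95% of differences ran from -0.89 to 1.4.

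The probe sets past the limit in both lines were 60.8% of those higher in wt and 30.7% of those lower in wt. BZIP61 (log2 -1.97 in wt and -2.26 in opr3) and BHLH101 (about -1.80 and -1.91, with wounded values near background) were lower in both lines, and AT5G62360, AT4G30650, AT5G05600 and AT5G55180 were higher by similar amounts in both. Of the 576 probe sets higher in wt, 350 were higher in opr3 as well, where independent lists of these sizes would share 27.9. The lower lists shared 80, against 4.38 for independent lists. The lines share no array, and across probe sets the differences correlated with Pearson's r of 0.68 and Spearman's rho of 0.63.

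Part of the wt response was smaller in opr3, including that of 3 of the 4 measured jasmonate turnover genes. Relative to wt, the response in opr3 was 21.8-fold smaller for AT2G38240 and, with values near background in 3 arrays, about 36.3-fold for BSMT1, about 24.6-fold for JRG21 and about 3.33-fold for JMT. The turnover list had a median difference of responses of -3.09, with AT5G05600 at 0.09 as its exception. Since the filter decided in part which genes it held, this size depends on the filter, and without it the median was -1.74. TBL26, of a family that acetylates cell wall polysaccharides, was 10.2-fold higher in wounded wt and had a log2 response of -0.11 in opr3. AT2G43550 and AT1G54020 had responses 5.89-fold and about 4.43-fold smaller. Of the 576 probe sets higher in wt, 132 had a response at least 2-fold smaller in opr3, 414 lay within 2-fold and 30 were at least 2-fold larger. Sets chosen for one line favour that line, and of the 708 higher in opr3, 152 had a response at least 2-fold larger than in wt.

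Of the metabolic genes in short lists, APS3 had a response 2.03-fold smaller in opr3, while AT2G04400 (1.89-fold), UGT74B1 (1.83-fold), AT2G31790 (1.88-fold), SIR (1.64-fold) and OPCL1 (1.53-fold) were under the limit. BCAT4 and AIM1 had differences of 0.04 and 0.20. The MYC-branch list had a median difference of 0.27 (percentile 89.7). In it the response in opr3 was about 3.58-fold larger for GRX480 and about 2.13-fold smaller for THI2.1. Most of the GRX480 difference lay in controls, where opr3 was at about -1.39 relative to wt, against 0.45 after wounding. The 4 touch and calcium genes had a median of -0.34 at percentile 1.63, led by CML38 at -1.32. In controls this list lay higher in opr3 than in wt (median 0.51), and after wounding lower (median -0.28). CML38 was at 0.82 in controls and -0.50 after wounding. AT4G29780 and the transcription factor gene WRKY22 were 7.66-fold and 4.69-fold lower in the difference of responses, and both started from a higher level in opr3 controls.

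Larger in opr3 was the response of AT5G55450, a lipid-transfer family gene, by 11.8-fold, of AT2G43620 by 8.43-fold, of AT4G00700 by about 8.0-fold, of AT5G03350, a legume lectin family gene, by 6.76-fold and of AT1G13470 by 6.65-fold. Each of these 5 genes was lower in opr3 than in wt controls, by log2 -1.22 to -1.53, and higher in opr3 than in wt after wounding. CYP71B23 and AT1G72060 followed at 4.82-fold and 4.66-fold. COR15A had a response 2.24-fold larger in opr3, and the abscisic acid list a median difference of 0.85 at percentile 99.7. Most of the COR15A difference lay in controls, where opr3 was at -0.85 relative to wt, against 0.31 after wounding, and the list median was -0.25 in controls (percentile 1.67) and 0.31 after wounding (percentile 94.7). Plastid genes made up 21 of the 302 probe sets at least 2-fold higher in this difference, among them psaA, atpH, psaC, ndhH and psbD, and the wt wounded array that enters it had the lowest spiked-in 5' minus 3' value. Over 7791 nuclear genes the difference of responses correlated with genomic length at Spearman's rho of 0.15 (-0.06 for the wt response and 0.07 for the opr3 response), across genes, which are not independent replicates. A further 193 probe sets were lower. The difference of responses was not tested, since each combines 4 single arrays.

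**Figure D2:**
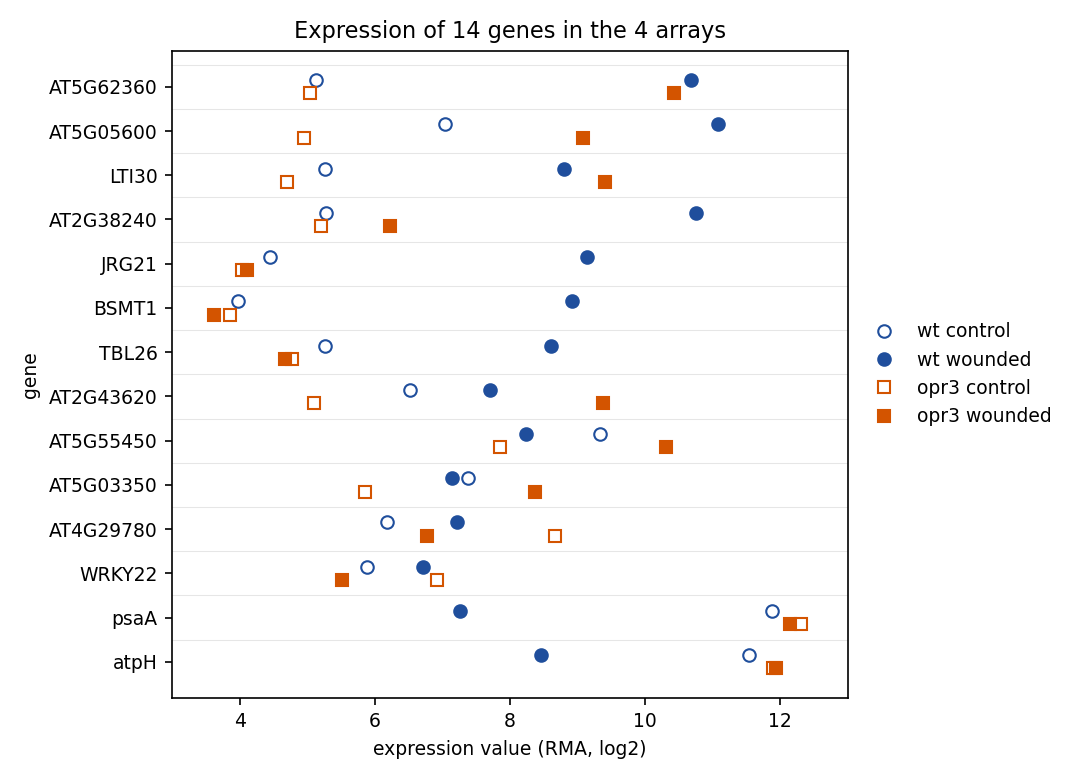
RMA expression values (log2, x axis) of 14 genes (y axis) in the 4 arrays, with circles for wt, squares for opr3, open symbols for control and filled symbols for wounded plants. JRG21 was at 9.13 in wounded wt and at or under 4.44 in the other arrays, and psaA was at 7.27 in wounded wt and at or above 11.87 elsewhere.

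Before wounding, opr3 differed from wt in fewer probe sets. AT4G29780 was 5.64-fold higher in opr3 controls, EXO, a brassinosteroid-responsive gene, 4.40-fold, AT2G24600 3.53-fold, AT1G33760, an ERF-family transcription factor gene, about 2.94-fold, AT1G05575 2.73-fold and the ubiquitin ligase gene PUB23 about 2.55-fold. WRKY53 was 2.15-fold and STZ, a zinc finger transcription factor gene, 2.07-fold higher, and the median of the 3 rapid stress transcription factors measured out of 22 written was 1.05, at percentile 99.99, with WRKY6 at 0.12. The 3 auxin genes had a median of 0.64 (percentile 99.98, mean 0.40), with none past the limit and WES1 at -0.27. That median is the value of GH3.3, near background in wt control. In contrast, the MYC-branch list had -0.40 (percentile 0.36, mean -0.53), with GRX480 at about -1.39, near background in opr3 control. The turnover list had -0.59, below all 10000 random lists, or -0.41 without the filter and -0.84 as a mean. Its median rests on JMT (-0.77) and JRG21 (-0.41), which lay under the filter level in both control arrays. Random lists were matched on the mean of all 4 arrays, which wounded wt raised for these genes, so the rank says little. CML42 was 2.11-fold higher and CML38 1.77-fold, against CML41 at about 2.22-fold lower. The touch and calcium median was 0.51 (percentile 99.97), but its size varied, with a mean of 0.24, and medians of 0.36 without the filter and 0.82 with the filter at the 60th percentile. Lower in opr3 controls were AT3G28220 (4.37-fold), AT5G05600 (4.26-fold), AT3G51450 (3.40-fold), JAL23 (about 3.33-fold), AT2G39420 (3.03-fold), AT5G03350 (2.88-fold) and the chitinase gene CHI (2.84-fold).

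Several of the remaining genes lie close together on chromosome 5. AT5G02140 was about 6.93-fold higher in opr3 controls, AT5G01350 3.66-fold, Fes1C (AT5G02150) 3.42-fold and AT5G02170 about 2.95-fold, while AT5G01015 was about 6.55-fold lower. They kept their direction in the wounded arrays, at about 6.11-fold, 3.12-fold, 2.90-fold and about 2.02-fold higher and about 6.13-fold lower. The plastid gene rpl20 was 2.71-fold higher in opr3 controls and AT1G69890 2.51-fold. The 69 plastid-encoded probe sets had a median of 0.28 between the control arrays, against -0.04 for the rest, with 3 at least 2-fold higher in opr3. In all, 61 probe sets were at least 2-fold higher in opr3 controls and 84 lower, and the central 95% of differences ran from -0.56 to 0.46.

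After wounding, the lines were further apart, with the jasmonate turnover genes much lower in opr3. BSMT1 was about 39.4-fold lower in opr3 than in wt, JRG21 about 32.7-fold, AT2G38240 23.0-fold, TBL26 about 15.3-fold, AT2G43550 12.7-fold and JAL23 11.9-fold, and the 4 turnover genes had a median of -3.52, or -2.51 without the filter. The defensin genes PDF1.2 (2.07-fold) and PDF1.2b (2.1-fold), UGT74B1 (2.69-fold), AT2G04400 (2.45-fold), APS3 (3.38-fold) and SIR (2.1-fold) were lower too, which covers every measured member of the lists of ERF-branch, tryptophan and indole glucosinolate, and sulfur genes. These 6 genes were already lower in opr3 controls, by between 1.28-fold (SIR) and 1.72-fold (PDF1.2b). The probe set of PDF1.2b has a suffix for possible cross-hybridization, so its value may not be separate from that of PDF1.2. The MYC-branch list, with 4 of 17 members measured, had a median of -0.13 (percentile 17.0), with THI2.1 about 2.05-fold lower and GRX480 at 0.45. GH3.3 was 2.30-fold higher in opr3, the only 1 of the 3 auxin genes past the limit. Their median was 0.94 at percentile 99.99, against 0.64 in controls, where none was past the limit and WES1 was at -0.27. Among 195 probe sets at least 2-fold higher in opr3, 26 were plastid-encoded, and the wt array compared here is the one with the lowest spiked-in 5' minus 3' value. The median of all 69 plastid-encoded probe sets was 0.66 here and already 0.28 in controls. The number lower was 242, and the central 95% of differences ran from -0.76 to 0.79.

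Of the 145 probe sets at least 2-fold apart between the control arrays, 51 were at least 2-fold apart in the same direction between the wounded arrays, which are separate arrays. Among these 51 probe sets, 41 were lower in opr3 and 10 higher. The lower ones included AT5G05600 (4.26-fold in controls and 3.99-fold after wounding), AT3G28220 (4.37-fold and 4.59-fold), JAL23 (about 3.33-fold and 11.9-fold), CML41 (about 2.22-fold and 2.19-fold) and AT1G62660, a vacuolar invertase gene (2.26-fold and 6.63-fold). Another 20 of the 145 probe sets were at least 2-fold apart in the opposite direction between the wounded arrays.

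**Figure D3:**
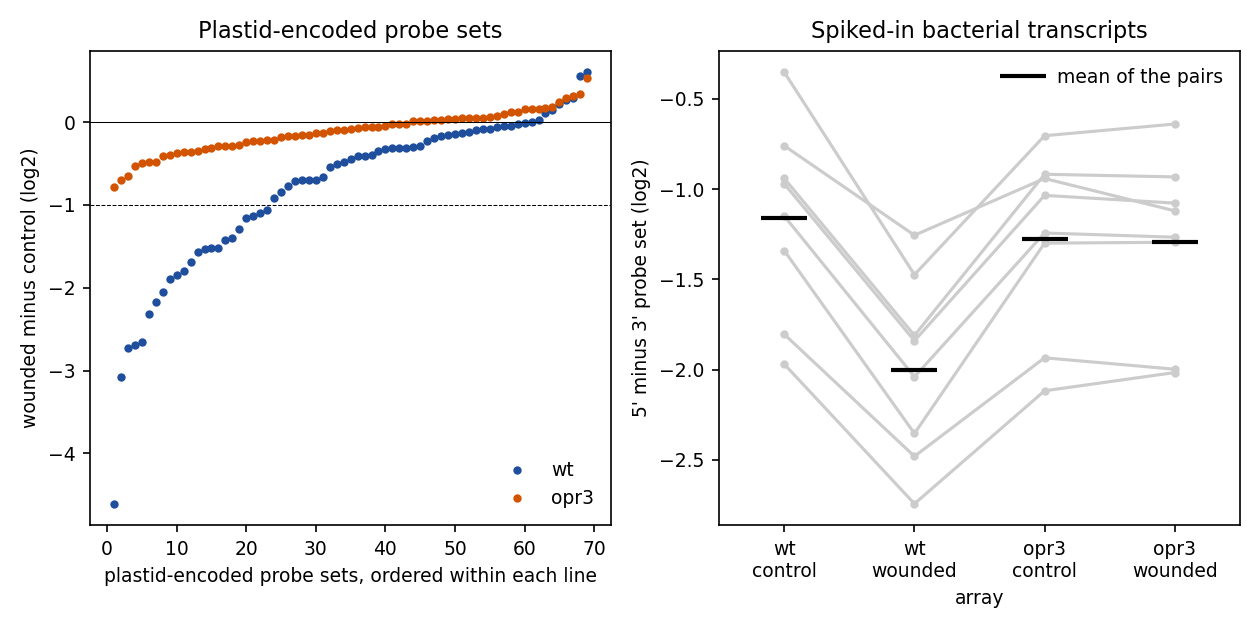
Left, wounded minus control (log2, y axis) of 69 plastid-encoded probe sets ordered by value within wt and within opr3, with a dashed line at 2-fold. Right, 5' minus 3' log2 difference of 8 pairs of spiked-in probe sets in each array (grey, joined by pair) with their mean (black), which was -2.00 in wounded wt and between -1.29 and -1.16 in the other arrays.

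The 4 measured reference genes PEX4, AT4G34270, AT2G28390 and GAPC2 had medians of -0.10 in the wt response and -0.04 in the opr3 response, at percentiles 48.2 and 53.0. HCT of the phenylpropanoid list had log2 responses of 0.39 in wt and 0.91 in opr3, DFR of the anthocyanin list 0.11 and -0.19, and EIN3 of the ethylene list -0.28 and 0.28. DFR lay under the filter level in every array except opr3 control (4.79), so its responses are approximate. The evening clock gene GI had responses of -0.08 and 0.16, WRKY6, which was also written for senescence, 0.38 and 0.55, and the guard cell marker FMA -0.09 and -0.15. The root marker PYK10, the 3 named detoxification genes and the 2 named heat shock genes did not pass the filter in any array. The 18 hybridization control probe sets showed no 2-fold difference in any comparison.

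**Figure D4:**
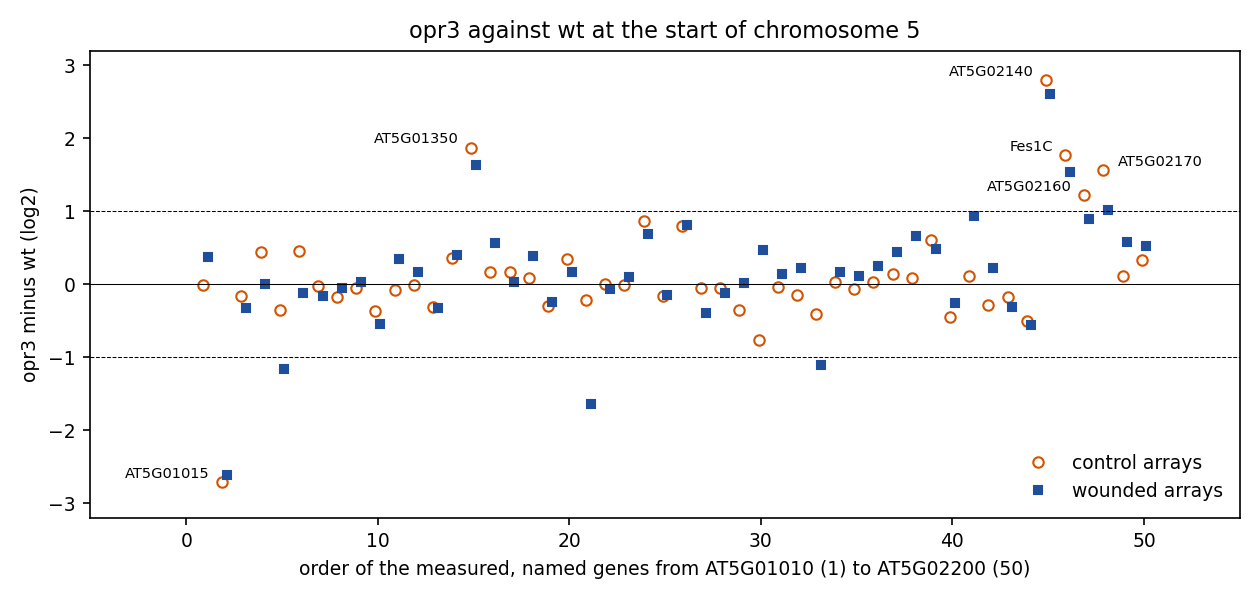
Log2 difference between opr3 and wt (y axis) for 50 consecutive measured named genes from AT5G01010 to AT5G02200 in their order along chromosome 5 (x axis), in control arrays (open circles) and wounded arrays (squares), with dashed lines at 2-fold. AT5G02140 was at 2.79 and 2.61 and AT5G01015 at -2.71 and -2.62.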

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

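All tests in this part were chosen only after the result was seen.

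AT5G55450, CYP71B23 and AT1G72060 were at least 2-fold lower in wounded wt and at least 2-fold higher in wounded opr3, and AT4G29780 went the other way. The responses differed by 3.56 (AT5G55450), 2.27 (CYP71B23), 2.22 (AT1G72060) and -2.94 (AT4G29780) on the log2 scale, opr3 minus wt. The unnamed probe sets 265837_at, 266385_at, 266070_at and 264147_at, chosen after their values were seen, behaved like AT5G55450, with differences of 4.58, 3.66, 2.68 and 2.34. These 8 probe sets were singled out because the single response of each line lay past the 2-fold limit in opposite directions, and the difference was not tested. In opr3 controls AT4G29780 was already 5.64-fold higher than in wt and AT5G55450 2.80-fold lower, so the opposite responses brought AT4G29780 to levels of 7.21 in wt and 6.77 in opr3.

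Spiked-in bacterial transcripts, which no comparison used, had a 5' minus 3' difference in the wt wounded array that lay at -0.757 (log2) relative to the mean of the other arrays, lower in all 8 pairs, with an SD over pairs of 0.227 and a range of 0.132 among the other 3 arrays, while 4 pairs of plant transcripts had -0.399 (SD 0.271) and were lowest in this array in 3 of 4. The pairs repeat transcripts (dap, lys, phe and thr for the spikes, actin and GAPDH for the plant). They are therefore not independent, and the SD over pairs is not a spread between separate transcripts. In the wt wounded array 23 of 69 plastid-encoded probe sets were at least 2-fold lower than in wt control. A uniformly lower share of plastid RNA is argued against by the spread of the 49 plastid probe sets of intermediate level, whose SD was 4.81 times as large in the wt response as in opr3. A stronger loss of 5' sequence in labelling is a candidate explanation: over 13 plastid transcripts that several genes share, ordered 5' to 3' from general knowledge and not from the tables, the 5' gene minus the 3' gene had a median of -0.825 in wt relative to opr3 with an SD of 1.72, below 0 in 10 of 13, and was below 0 in 10 of 13 within each line (medians -1.02 in wt and -0.19 in opr3). Only the end genes of each transcript were compared, and some inner genes lay below both ends in the wt response. In the transcript from rps2 (-0.45) to atpA (-0.91), inner gene atpH was at -3.08. Between ndhH (-2.65) and ndhD (-0.41), psaC was at -2.69. A steady rise from the 5' to the 3' end was thus not seen in these transcripts. An effect of wounding in wt that opr3 lacks stays open, since the median difference of responses of 0.359 rests on single arrays.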

How the results depend on the processing

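The alternatives here were planned, except leaving out plastid-encoded genes, which was chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. A log transform was not run because the values are log2. Under the 3 other scalings, no filter, the 60th percentile filter, only probe sets without a suffix and no plastid-encoded genes, every count of probe sets stayed within 1.5 times its value. Shared counts were run under the 3 scalings and no filter only, and stayed within it. All 145 differences of named genes kept their sign under the 3 scalings, and 143 or 144 stayed past 2-fold. Little else could result, since these differences were chosen past the limit and RMA had already quantile normalized the values. Of list medians, 256 moved by less than the SD of random lists and 19 by more, and none outside the central 95% of random lists turned sign. Inside it, the auxin median in wt (-0.21, percentile 26.1) became a mean of 0.43, and the others that turned lay within 0.08 of 0.

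Changing the limit moved all counts, as its construction requires. With 1.5-fold, higher and lower counts were 1216 and 1243 in wt, 1649 and 1124 in opr3, 243 and 332 for opr3 against wt in controls, 717 and 550 after wounding, 1114 and 622 for the difference of responses, and 820 and 518 for the overlap. With 3-fold they were 251 and 43, 279 and 36, 11 and 25, 45 and 122, and 92 and 75.

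Without the filter AT3G11180 and further weak genes entered the lists. The turnover medians were then 4.04 (wt), -1.74 (difference of responses), -0.41 (controls) and -2.51 (after wounding), and the touch and calcium medians 0.68 (wt) and 0.36 (controls). At the 60th percentile the latter were 0.58 (opr3), 0.82 (controls) and -0.50 (after wounding), with fewer genes. Means in place of medians gave 1.57 (opr3), -0.84 (controls) and -2.68 (difference) for turnover, 0.55 (opr3) and -0.53 (controls) for the MYC branch, -0.22 (opr3) and 0.76 (controls) for rapid transcription factors, 0.24 (controls) for touch and calcium, and 0.40 (controls) for auxin; the cause is the construction, since lists of 3 or 4 genes follow single members in a mean. How far signal over background limits weak genes was not measured, since the 8134 probe sets under the filter follow from the percentile chosen.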

Other observations

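The tests and families in this part were chosen only after their values were seen.

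Glycosyltransferases named UGT, which attach sugars to small molecules, had a median above 0 in wounded wt. Of 23 measured UGT genes, 7 were at least 2-fold higher in wt, and in opr3 1 was higher and 1 lower (UGT85A5), but only 2 had responses at least 2-fold apart, as UGT84A3 and UGT71B1, both at 0.87 in opr3, lay just under the limit there. The family had medians of 0.27 (percentile 99.95 of matched random lists) and 0.09 (percentile 88.8). UGT76E12 had log2 responses of 1.91 in wt and 0.07 in opr3, with values near background in 3 arrays, and UGT78D1, a flavonol glycosyltransferase, 1.13 and -0.37, while UGT76E11 had 1.25 and 1.09. The median difference of responses was -0.23 and lay between -0.34 and -0.28 under the 3 other scalings.

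TBL genes, besides TBL26, included TBL37 with responses of 1.74 in wt and 0.53 in opr3, and the 15 measured members had medians of 0.24 and 0.08. Among 8 ubiquitin ligase genes named PUB, PUB23 had responses of 1.1 and -0.98 and PUB25 -0.51 and -1.57, both approximate because PUB23 in wt control and PUB25 in wounded opr3 lay near background, and the family median was 0.25 higher in opr3 than in wt controls. PUB19 went the other way in controls, at -0.88. Sugar transporter genes named SWEET varied by member: SWEET17 was at 1.12 in wt and 0.63 in opr3, and SWEET13 at about -1.26, with a value near background in wounded wt, and -0.31. Of 7 beta-glucosidase genes, BGLU25 was similar in both lines (2.02 and 2.08).

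Genes at least 2-fold apart between the control arrays of opr3 and wt crowded at the start of chromosome 5, where 6 of 51 such genes fell in a window of 50 consecutive measured genes out of 7791, among them AT5G01015, AT5G01350, AT5G02140, Fes1C and AT5G02170. Noise between the 2 control arrays is argued against by the wounded arrays. In these, 5 of the 6 genes were at least 2-fold apart in the same direction, compared with 11 of the 45 genes elsewhere. The sixth, AT5G02160, was at 0.90. The 11 genes elsewhere include AT5G02480, which lies shortly past the window, at 1.08 in controls and 1.13 after wounding. A linked chromosome segment that differs between the opr3 and wt lines is a candidate explanation, since 5 of 10000 random placements filled a window as much. No such gene lay among the 50 measured genes around the OPR3 locus on chromosome 2. Whether the values reflect transcript levels or sequence differences under the probes was not tested.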
